A study of Rattus norvegicus with 12 samples.

How the data were processed

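The series holds 12 libraries of male rat hippocampus: 6 RNA libraries and 6 small RNA libraries, with 3 libraries from rats kept in normoxia (control) and 3 from rats exposed to chronic intermittent hypoxia (CIH) for 4 weeks in each set. Total RNA was extracted with TRIzol and sequenced on BGI instruments, per the labels' protocols. The submitters' processing notes list Bowtie2 2.2.5, RSEM 1.2.12, HISAT2 2.2.0 and the genome build Rnor_6.0, with no role or order. The annotation, the use of strand, the miRNA counter and any molecular identifiers are not given in the sources used here.

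The RNA table gives, per the file headers, estimated read counts, TPM and FPKM for 26949 genes. The deposited estimated counts are not whole in 16.0% of values and were rounded to whole numbers before testing. The TPM values made by the authors served for an alternative test only, and the FPKM values made by the authors were not used in any test. The small RNA table gives, per the file headers, whole-number read counts and a normalized value for 669 known and 834 predicted miRNA names. The deposited small RNA counts were used as they stand. The authors' normalized small RNA value, an RPM-type unit, equals the count divided by 1 number per library, between 17.3 and 18.4 counts per unit, and served for an alternative test only. What that number stands for is not given in the sources used here. Predicted miRNAs held 1.09% of the small RNA counts. RNA totals were 17170943 to 21941173 estimated counts per library, and small RNA totals were 4681163 to 4914232 counts.

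Samples were grouped by their titles. Each set was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Filtering left 17935 genes and 715 miRNAs. A log2 fold change is CIH over control, and its standard error (SE) was derived from the fold change and the F statistic. CPM values are counts scaled by the TMM-adjusted totals. Gene and miRNA lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, over 35 of 36 gene lists and 8 of 9 miRNA lists with at least 3 tested members. The lists hold markers of hippocampal fields, neighbouring brain tissue, glia, vessels and blood, and pathway genes. A list score is the mean log2 CPM of the members minus their mean over the 6 libraries. The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took genes past the threshold with no overlap between the groups and a mean log2 CPM above 1, filled to 10 genes and 8 miRNAs with the smallest p, up to 4 members of each list, and a fixed set of hypoxia, immune, activity and tissue genes. The genes used to fill the 10 also had to show no overlap and such a mean. Any other gene named was chosen after its values were seen. One gene that the rule named is not reported here.

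The tests were checked on simulated counts with the means and totals of these libraries. In the RNA simulation over 17935 genes, 34% of 100 genes changed 1 log2 unit and 78% of 100 genes changed 2 log2 units were called, with 8 false calls. In the small RNA simulation over 715 miRNAs, 4% of 50 changed by 1 log2 unit and 14% of 50 changed by 2 log2 units were called, with 1 false call. A log2 shift of 0.5 in 1 simulated list was found among 35 lists with no other list called. Genes and miRNAs were drawn independently of each other, so simulated list members did not vary together. In these libraries the estimated correlation ran from -0.0142 to 0.737 over the lists that camera called. The simulation therefore cannot show how often lists are called wrongly here.

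The alternatives were another normalization (RLE), no low-count filter, DESeq2 1.42.0, limma on the log2 of the authors' normalized values with a pseudocount of 1 or 0.1, the replicate number as a block, and leaving out each library. Lists were also tested with an estimated correlation and with fry. Sample quality weights, a dentate covariate and summed counts of miRNAs with overlapping precursors were chosen after seeing the data. The overlaps were read from a RefSeq gene table of the GRCr8 assembly, used only for names and for which genes overlap: 659 of 669 known miRNA names and 19709 gene identifiers were matched. Overlap was judged by position without regard to strand. Names were joined by precursor gene, so sums of all overlapping names can pool both arms of a hairpin. A test of seed-site genes was not run, because no miRNA passed the threshold and no 3' UTR sequence was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.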

Results

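Hippocampal RNA and small RNA were profiled in male rats after 4 weeks of chronic intermittent hypoxia (CIH), repeated cycles of low oxygen used as a model of sleep apnoea, or of normoxia (control). Each assay had 3 libraries per group. RNA totals were 17170943 to 21941173 estimated counts and small RNA totals 4681163 to 4914232 counts per library. No pair of libraries agreed within sampling noise (a chi-square of at least 6.98 per degree of freedom for every pair). The labels do not say whether the 3 libraries of a group came from separate animals, so the tests measure the spread between these libraries. Correlations of log2 CPM between RNA libraries were as high between the groups (0.956 to 0.985) as within them (0.957 to 0.983).

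The first comparison asked which mRNAs differ between CIH and normoxia. Nes (gene ID 25491), which encodes the neural progenitor filament nestin, stood at 14.4 ± 0.585 CPM in control and 8.43 ± 1.35 CPM in CIH (SD, n = 3 each), a log2 fold change of -0.77 (SE 0.16). Vegfa (gene ID 83785), the hypoxia-inducible angiogenic factor, stood at 72.4 ± 5.10 CPM in control and 89.6 ± 1.79 CPM in CIH (SD, n = 3 each), a log2 fold change of 0.31 (SE 0.10). Thrsp (gene ID 25357), a regulator of lipid synthesis, had a log2 fold change of 0.85 (SE 0.20), and Frem1 (gene ID 298185), an extracellular matrix protein gene, one of -1.24 (SE 0.22). In each of these 4 genes the CIH libraries did not overlap the controls, which for Nes, Thrsp and Frem1 was a condition of their choice. None passed the edgeR test after Benjamini-Hochberg adjustment (adjusted p = 1.00 for each). DESeq2 called Frem1 (adjusted p = 0.00887), while its adjusted p in the other alternatives ran from 0.661 to 1.00.

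No gene among 17935 tested passed the edgeR threshold; the smallest adjusted p was 0.520, for both Wbp11l1 and NEWGENE_1306267. The latter, chosen after its values were seen, had 0 counts in each control and 42, 46 and 34 in CIH. At an unadjusted p under 0.05 there were 319 genes, 164 of them higher in CIH, where chance alone gives 897. DESeq2 called 10 genes, 3 higher (NEWGENE_1306267, LOC103690996 and LOC691320) and 7 lower (Wbp11l1, Frem1, Exoc7, LOC108350558, LOC108349748, LOC108351211 and Galr1); LOC103690996, LOC691320 and Galr1 were chosen after their values were seen. The groups did not overlap for 1022 genes, or 5.70%, where chance gives 10%. Wbp11l1, a copy of the splicing factor gene Wbp11, had a log2 fold change of -2.43 (SE 0.28), while Wbp11 itself, chosen after its values were seen, had one of 4.13 (SE 0.95). These copies may share reads, which was not tested, so each is uncertain singly. Their summed counts gave -0.14 (SE 0.11). The other genes chosen by smallest p had to show no overlap between the groups and a mean log2 CPM above 1. They were the exocyst gene Exoc7 at -1.79 (SE 0.33) and the uncharacterised loci LOC108350558 at -2.25, LOC108349748 at -2.28, LOC108351211 at -2.55, LOC100911516 at -0.74 and LOC100911261 at 1.06. Without control replicate 3 the edgeR test called 1 gene (Wbp11), and without CIH replicate 2 it called 1 (Wbp11l1).

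Genes of the hypoxia, inflammation and activity response named in advance did not pass the test. Hif1a, the oxygen-regulated transcription factor, had a log2 fold change of 0.08 (SE 0.17), and the neurotrophin gene Bdnf one of 0.03 (SE 0.22). The astrocyte filament gene Gfap stood at 0.07 (SE 0.40), the microglial gene Aif1 at 0.28 (SE 0.21), and the immediate early gene Fos at 0.34 (SE 0.52). The choroid plexus gene Ttr stood at -0.43 (SE 1.18) and the haemoglobin gene Hbb at 0.11 (SE 0.48). None of these 7 passed the edgeR test (adjusted p = 1.00 for each), and leaving out 1 library turned the direction of all but Aif1. Ttr stood at -3.08 without CIH replicate 3, 0.31 without control replicate 1, 0.13 without CIH replicate 1 and 0.03 without CIH replicate 2. Over the left-out libraries Fos ran from -0.38 (CIH replicate 1) to 0.75 (control replicate 3), Hbb from -0.46 (CIH replicate 1) to 0.45 (CIH replicate 3), Gfap from -0.20 (control replicate 2) to 0.65 (control replicate 1), Bdnf from -0.18 (control replicate 2) to 0.15 (control replicate 3) and Hif1a from -0.03 (CIH replicate 3) to 0.23 (control replicate 1). The cytokine genes Il1b and Tnf had at most 1 and 7 counts per library, so a difference was not detectable at this depth.

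**Figure D1:**
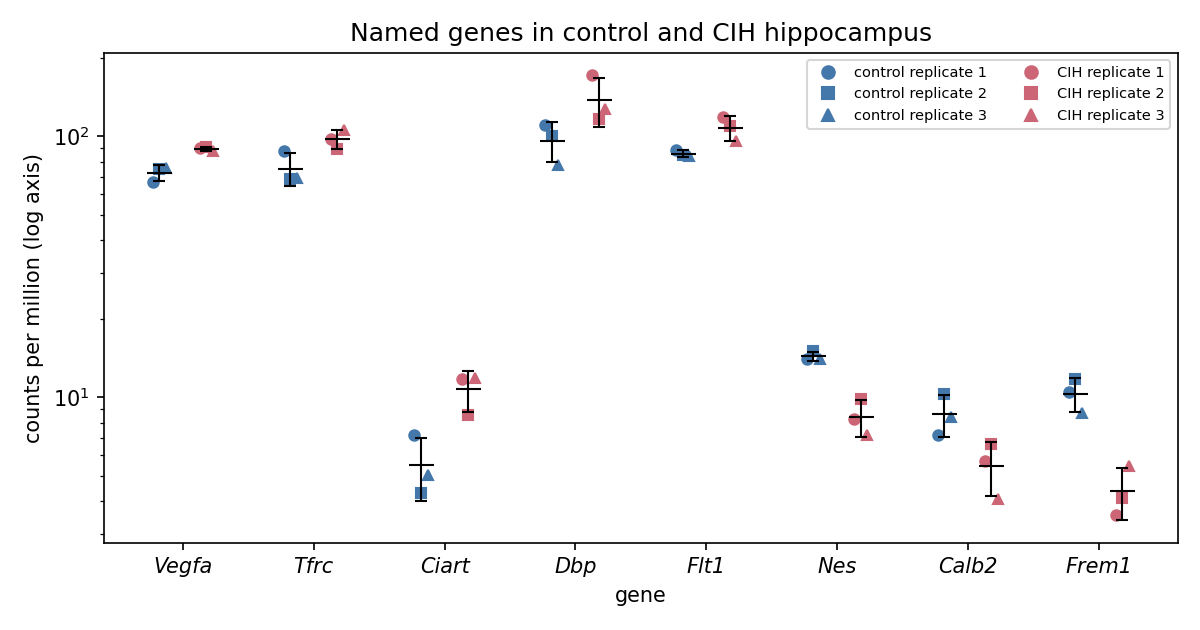
CPM (log axis) of 8 genes (Vegfa, Tfrc, Ciart, Dbp, Flt1, Nes, Calb2 and Frem1) in the 3 control and 3 CIH libraries. Black bars give the mean and SD of each group. The groups do not overlap for any of these 8, against 5.70% of all tested genes, and none passed the edgeR test. Named genes with overlap are not drawn. Vegfa stands at 72.4 ± 5.10 CPM in control and 89.6 ± 1.79 CPM in CIH, and Nes at 14.4 ± 0.585 and 8.43 ± 1.35 CPM.

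The second comparison asked which groups of genes, fixed before the data were examined, differ between CIH and normoxia. The list of HIF-1 targets was higher in CIH, with 18 of 24 measured members higher and a median log2 fold change of 0.09; Tfrc, the transferrin receptor, stood at 0.38 (SE 0.13) and Kdm3a, a histone demethylase, at 0.18 (SE 0.10), while the glucose transporter gene Slc2a1, chosen after its values were seen, stood at 0.02 (SE 0.09). The list of neurogenesis and proliferation genes, called neurogenesis here, was lower in CIH, with 7 of 10 members lower and 3 higher. Of its members with the smallest p, beside Nes, the calretinin gene Calb2 stood at -0.66 (SE 0.23), Igfbpl1 at -0.66 (SE 0.31) and the immature neuron gene Dcx at -0.40 (SE 0.28). In both lists every CIH library scored beyond every control. HIF-1 target scores were 0.01, 0.06 and 0.07 in CIH against -0.10 to -0.01 in control. Neurogenesis scores were -0.39 to 0.02 in CIH against 0.12 to 0.17 in control. Chance alone separates 3 libraries from 3 in 10% of lists, and the HIF-1 gap was narrow, from -0.0101 in control replicate 1 to 0.0052 in CIH replicate 1. Camera gave adjusted p = 0.0301 for the HIF-1 targets and 0.0245 for neurogenesis. With an estimated correlation the adjusted p was 0.736 for both. That correlation was -0.0142 for the HIF-1 targets and 0.0213 for neurogenesis, near the preset 0.01. The unadjusted camera p with it was 0.0382 and 0.052. The HIF-1 call was also lost with the dentate score as a covariate, an alternative chosen after seeing the data (adjusted p = 0.0827), and without control replicate 1 (adjusted p = 0.144), control replicate 2 (0.145), CIH replicate 2 (0.211) or CIH replicate 3 (0.103), and the neurogenesis call without control replicate 1 (0.165), CIH replicate 2 (0.0560) or CIH replicate 3 (0.124). No member of either list passed the edgeR test over all genes. Adjusted over the list alone, 1 neurogenesis gene, Nes, passed the edgeR test (adjusted p = 0.0171). That adjustment was made within each of 35 lists singly and not across lists, so 1 passing gene may arise by chance.

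The circadian clock list was higher in CIH, with 14 of 16 members higher. Ciart, a repressor of the clock, stood at 0.96 (SE 0.24), the clock output gene Dbp at 0.52 (SE 0.19) and the repressor Nr1d1 at 0.57 (SE 0.25). Of 4 members in the opposite phase, chosen after their values were seen, Arntl stood at -0.16 (SE 0.13), Clock at 0.03 (SE 0.11), Cry1 at 0.12 (SE 0.15) and Npas2 at 0.34 (SE 0.56). The CIH libraries did not overlap the controls for Ciart, Dbp and Nr1d1, but the list scores overlapped, at 0.03, -0.12 and -0.26 in control and 0.36, -0.09 and 0.09 in CIH. CIH replicate 1 had the highest score, and 9 of the 16 members were highest in it. Camera gave adjusted p = 0.00313, against an adjusted p of 0.736 with an estimated correlation, 0.0827 with the dentate covariate, 0.175 without CIH replicate 1 and 0.0535 without control replicate 3.

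The myelin list was higher in CIH, with 14 of 16 members higher: the myelin genes Mbp and Mag stood at 0.45 (SE 0.40) and 0.41 (SE 0.35). Its scores were 0.42, -0.46 and -0.45 in the control libraries and -0.13, 0.11 and 0.51 in the CIH libraries, so the groups overlapped. Camera gave adjusted p = 0.00257, against an adjusted p of 0.792 with an estimated correlation, 0.112 without control replicate 2, 0.139 without control replicate 3 and 0.287 without CIH replicate 3.

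Markers of vessels, blood and cortex were higher, and those of dentate granule cells and choroid plexus lower, in CIH. All 16 endothelial and pericyte genes were higher, with the VEGF receptor gene Flt1 at 0.33 (SE 0.11) and the adhesion gene Pecam1 at 0.52 (SE 0.23). All 8 erythroid genes were higher, with the haemoglobin gene Hbb-b1 at 0.77 (SE 0.47), and 8 of 9 cortical layer genes, with Lamp5 at 0.56 (SE 0.26). Hbb-b1 had a mean of 2.40 CPM in control and 4.08 CPM in CIH. The more abundant haemoglobin gene Hbb, at 11.2 and 12.1 CPM, had a log2 fold change of only 0.11 (SE 0.48). All 8 dentate granule genes were lower, with the desmoplakin gene Dsp at -0.86 (SE 0.54) and C1ql2 at -0.70 (SE 0.44), as were 7 of 10 choroid plexus genes, with Kl at -0.73 (SE 0.45). Some erythroid and choroid plexus members had few counts per library: 3 to 15 for Hba-a3, 8 to 33 for Kl and 2 to 22 for Folr1. CIH replicate 1 stood apart in the vessel, cortex and dentate lists: its score was 0.60 for vessels, 0.81 for cortex and -1.32 for dentate granule genes, and each of the 16 vessel genes was highest in it. In CIH replicates 1, 2 and 3 the erythroid scores were 0.63, 0.37 and -0.21 and the choroid plexus scores -0.42, -0.73 and 0.20. Camera gave adjusted p = 0.000127 for vessels, 0.00257 for erythroid, 0.0216 for dentate, 0.0409 for cortex and 0.0468 for choroid plexus genes; without CIH replicate 1 these became 0.803, 0.155, 0.803, 0.804 and 0.0733, and with an estimated correlation the adjusted p was 0.736 for each. With the dentate covariate, which leaves the dentate list untested, the adjusted p was 0.292 for vessels, 0.119 for erythroid, 0.809 for cortex and 0.196 for choroid plexus genes. Other libraries also ended calls: for the erythroid list CIH replicate 2 (adjusted p = 0.0752 without it), for the dentate list control replicate 1 (0.520) and CIH replicate 2 (0.0628), for the cortex list control replicate 1 (0.333) and control replicate 3 (0.199), and for the choroid plexus list control replicate 1 (0.520) and CIH replicate 2 (0.638).

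In all, camera called 9 of 35 lists, 6 higher and 3 lower, and 0 with an estimated correlation. The other 26 lists, among them microglia, astrocytes, cytokines, interferon response, antioxidant genes, the unfolded protein response, apoptosis and glutamatergic synapse, had adjusted p from 0.0782 to 0.892. Of the 9 called lists, 3 were also called without CIH replicate 1: HIF-1 targets, neurogenesis and myelin. Adjusted over the list alone, 1 gene in all lists passed, a number that chance alone may give over 35 lists.

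**Figure D2:**
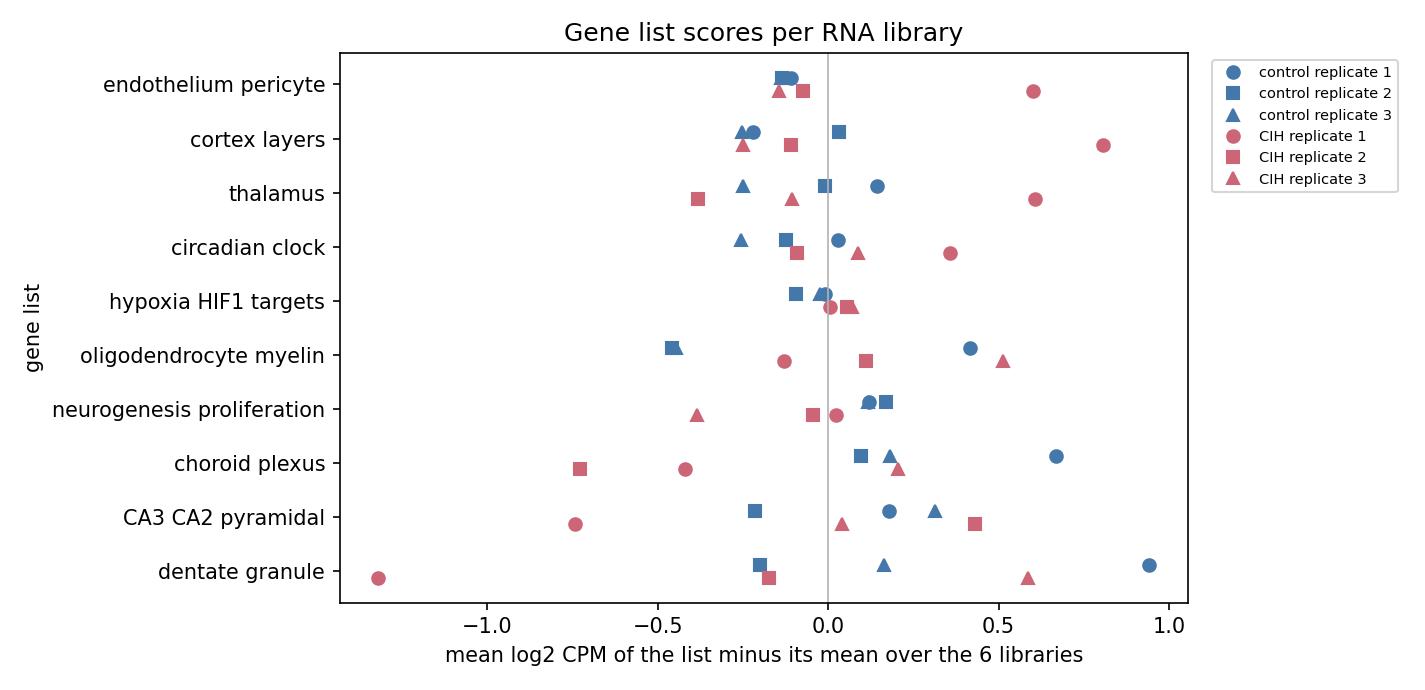
Mean log2 CPM of 10 gene lists in each RNA library, minus the list's mean over the 6 libraries; each point is 1 library. CIH replicate 1 scores -1.32 for dentate granule genes and 0.60 for vessel genes, and the HIF-1 target scores are 0.01 to 0.07 in CIH and -0.10 to -0.01 in control.

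The third comparison asked which miRNAs differ between CIH and normoxia. miR-219a-5p, an oligodendrocyte miRNA, stood at 1740 ± 359 CPM in control and 3320 ± 1110 CPM in CIH (SD, n = 3 each), a log2 fold change of 0.94 (SE 0.30), and miR-23a-3p at 0.48 (SE 0.17). miR-219a-5p summed with miR-219b and miR-219a-2-3p, to which overlapping precursor genes join it, gave 0.33 (SE 0.27); sums of this kind were chosen after seeing the data. miR-3557-3p had counts of 734, 953 and 1440 in control and 9, 33 and 5 in CIH, a log2 fold change of -6.02 (SE 0.85), and miR-378a-5p had 7, 8 and 50 in control and 1266, 1068 and 1332 in CIH, one of 5.81 (SE 0.90). The precursor genes of these latter names overlap, so their reads are uncertain singly; their summed counts gave 0.21 (SE 0.33). The remaining miRNAs with the smallest p were the predicted miR616-3p at -1.58 (SE 0.40) and miR606-5p at -2.53 (SE 0.71), miR-6331 at -1.70 (SE 0.47) and miR-296-3p at 1.15 (SE 0.34).

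None of 715 miRNAs passed the edgeR test; the smallest adjusted p was 0.174, for both miR-3557-3p and miR-378a-5p. At an unadjusted p under 0.05 there were 17 miRNAs, where chance gives 36, and DESeq2 called 2, miR-3557-3p and miR-378a-5p. The groups did not overlap for 55 miRNAs, or 7.69%, where chance gives 10%. Without control replicate 3 the edgeR test called miR-378a-5p alone, and without CIH replicate 2 miR-3557-3p alone.

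Among the miRNAs chosen before the data were examined, the hypoxia-induced miR-210-3p stood at -0.79 (SE 0.87), with counts of 135, 79 and 109 in control and 21, 16 and 152 in CIH. Its precursor gene overlaps that of miR-3574, chosen after its values were seen, which had 18, 24 and 14 in control and 199, 171 and 6 in CIH. Their summed counts gave a log2 fold change in the other direction, 0.56 (SE 0.28), with no overlap between the groups. The value of miR-210-3p alone was -2.55 without CIH replicate 3, -0.36 without CIH replicate 1 and -0.33 without CIH replicate 2. The neuronal miR-124-3p stood at 0.80 (SE 0.34), the activity-regulated miR-132-3p at 0.49 (SE 0.31), the erythroid miR-451-5p at 0.63 (SE 0.52) and the choroid plexus miR-204-5p at -0.26 (SE 0.18). The immune miRNAs miR-155-5p and miR-146a-5p stood at 0.02 (SE 0.40) and 0.13 (SE 0.28), and both turned direction without control replicate 3 (-0.29 and -0.09), the first also without CIH replicate 1 (-0.27). None passed the edgeR test (adjusted p from 0.969 to 0.996).

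No miRNA list of 8 passed camera (adjusted p from 0.0945 to 0.542). All 7 choroid plexus and cilia miRNAs were lower in CIH, with miR-211-5p, chosen after its values were seen, at -1.07 (SE 0.48), and all 3 oligodendrocyte miRNAs were higher; the adjusted p was 0.0945 for the first and 0.167 for the second. Each of the 7 choroid plexus and cilia miRNAs was lowest in CIH replicate 1, whose score was -1.31, while CIH replicates 2 and 3 (0.25 and 0.21) lay above control replicate 2 (-0.31). The adjusted p of this list ran from 0.000623 without control replicate 2 to 0.715 without CIH replicate 1. The hypoxia list had 4 of 7 members higher and a median of 0.00 against a mean of -0.24. Adjusted over the list alone, 0 miRNAs passed in any list. Between 1 and 2 lists were called when control replicate 1 (2), control replicate 2 (1) or CIH replicate 3 (1) was left out.

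**Figure D3:**
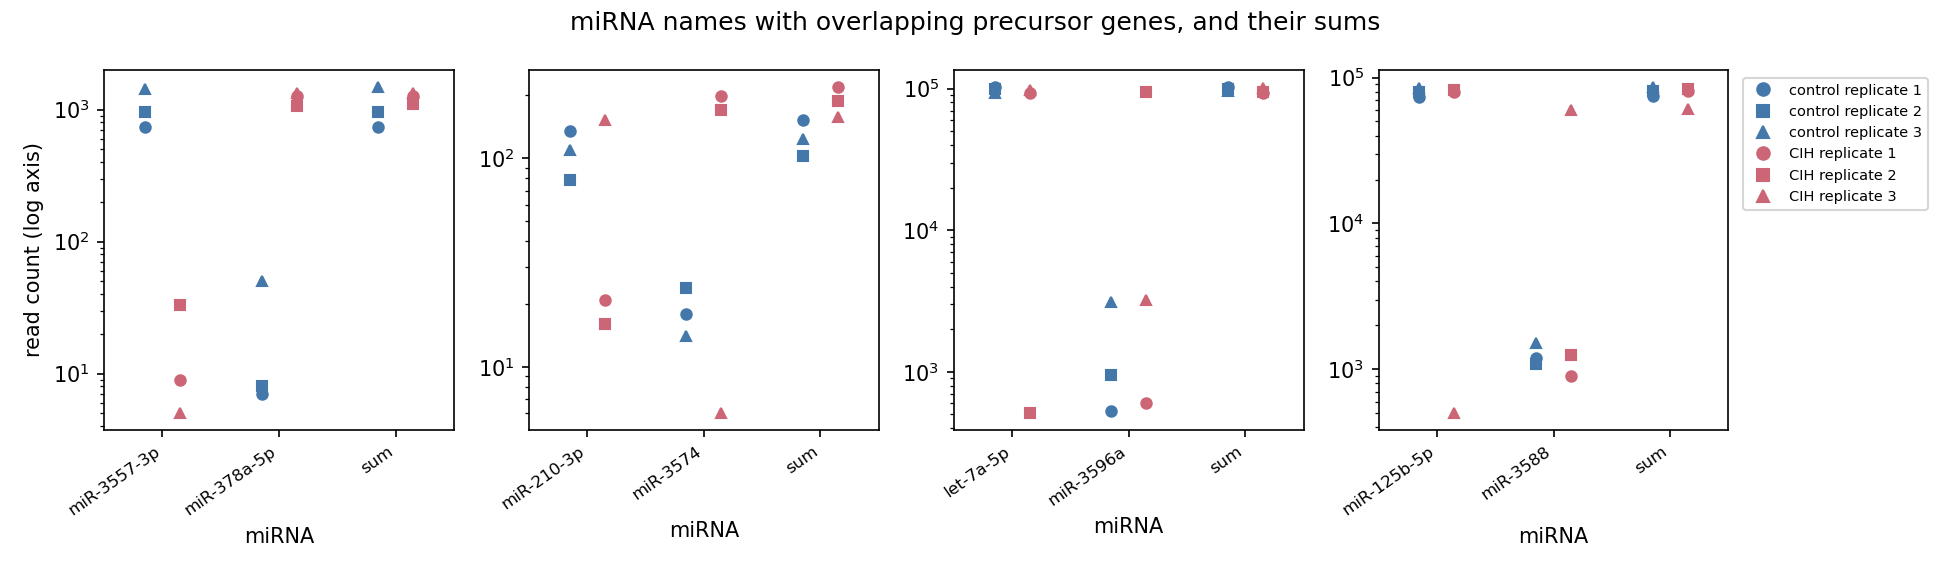
Read counts (log axis) of 4 pairs of miRNA names with overlapping precursor genes, and of their sums, in the 3 control and 3 CIH small RNA libraries; each point is 1 library. The sums of miR-3557-3p and miR-378a-5p lie between 741 and 1490 in all 6 libraries.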

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

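Sample quality weights, the dentate covariate and the summing of overlapping miRNA precursors were chosen after seeing the data. No mRNA passed with another normalization, no filter, limma on the authors' values, the dentate covariate or the replicate block (0 genes). DESeq2 called 10 and sample quality weights 1, and leaving out 1 library gave 0 to 1. For miRNAs, no filter, DESeq2 and each limma setting called 2, another normalization 0, the replicate block 0, summing 0, and leaving out 1 library 0 to 1. Camera called 9 gene lists, an estimated correlation 0 and fry 0. The dentate covariate called 5, of which 2 were among the 9 (myelin and neurogenesis); the others were meninges, striatum and glutamatergic synapse (adjusted p = 0.0324 for each). Leaving out 1 library gave 4 to 10 lists, of which 3 to 7 were among the 9. The replicate block called 7, all among the 9, without neurogenesis (adjusted p = 0.0513) and choroid plexus (0.0932). For miRNA lists, leaving out 1 library gave 0 to 2, and the replicate block 0. Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.222, -0.0457 and -0.176 in RNA and 0.122, -0.149 and -0.034 in small RNA. The cause of these differences was not tested. Of 33 genes and miRNAs, those with the smallest p and those fixed singly in advance, 23 kept their sign in each alternative that gave a value; miR-6331 had none with limma after the filter. The other 10 changed sign: Hif1a, Bdnf, Gfap, Fos, Hbb, Ttr, miR-155-5p and miR-146a-5p, and, on summing all overlapping names, miR-378a-5p (-0.09) and miR-210-3p (0.54). Such sums can pool both arms of a hairpin. miR-3557-3p, counted among the 23, also turned when summed with miR-378a-5p alone (0.21). In none of these changes did both values lie beyond 1 SE of 0. In counts simulated independently per feature, 34% of 1 log2 unit mRNA changes were found and 4% of such miRNA changes. Of unchanged simulated features, 4.91% of genes and 4.39% of miRNAs had an unadjusted edgeR p under 0.05. The data gave 319 of 17935 genes and 17 of 715 miRNAs, so these shares may not hold for these libraries.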

Other observations

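The tests chosen after the result was seen were the summed counts, the comparison of small RNA totals, the Fisher test, the other arm of miR-378a, the counts of cortex and dentate genes and of CIH libraries by dentate score, the clock arms, the relations between the assays, and the splits for mRNA and miRNA calls. Some genes of groups not described above had no overlap between CIH and control. The astrocyte bicarbonate transporter gene Slc4a4 had a log2 fold change of -0.27 (SE 0.10) and the metallothionein gene Mt1 one of -0.50 (SE 0.17). Among interneuron genes, the parvalbumin gene Pvalb stood at 0.42 (SE 0.15), while the GABA transporter gene Slc32a1 stood at -0.38 (SE 0.15) and the somatostatin gene Sst at -0.44 (SE 0.21), the last 2 with overlap. Among interferon-induced genes, Oas1a stood at 0.94 (SE 0.34), Mx2 at 0.55 (SE 0.20) and Psmb9 at -0.75 (SE 0.29), and Mx1, with overlap, at -2.37 (SE 1.01). None passed the edgeR test (adjusted p = 1.00 for each). Of the genes called by DESeq2, Galr1, a galanin receptor gene, had counts of 11, 236 and 240 in control and 8, 15 and 6 in CIH; LOC103690996 had 0 in each control and 118, 15 and 31 in CIH; and LOC691320 had 0 in each control and 46, 33 and 6 in CIH.

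The first pattern is the exchange of counts between miR-3557-3p and miR-378a-5p. Depth does not account for it, since the largest small RNA total was 1.05 times the smallest. The summed counts had a log2 fold change of 0.213 (SE 0.33), so the same reads may be given to either of the overlapping names in different libraries. Strand and sequence were not compared, so whether the names belong to 1 hairpin or lie on opposite strands was not tested. Among 362 known miRNAs with at least 200 counts in some library, 17 of the 27 that jump over 20-fold between libraries have an overlapping name, against 57 of the other 335 (two-sided Fisher's exact test, p = 5.77e-07, with the names of a pair counted as independent, which they are not). The 17 include miR-3557-3p and miR-378a-5p, which raised the hypothesis, and the let-7a-5p and miR-125b-5p pairs given below. The test therefore cannot serve as separate support for it. A change in the miR-378a precursor itself stays open, because miR-378a-3p, from its other arm, jumps as well (log2 fold change -1.31, SE 2.31).

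The same hypothesis bears on miR-210-3p: its counts summed with those of miR-3574 were 153, 103 and 123 in control and 220, 187 and 158 in CIH, a log2 fold change of 0.56 (SE 0.28) with no overlap between the groups. This sum did not pass the edgeR test (adjusted p = 0.972), and the sum of the 3 names with overlapping precursors gave 0.54 (SE 0.29). let-7a-5p and miR-3596a exchanged counts in CIH replicate 2 alone (510 against 94681), and miR-125b-5p and miR-3588 in CIH replicate 3 alone (499 against 60290); their sums gave -0.04 (SE 0.10) and -0.10 (SE 0.15).

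The second pattern is the distance of CIH replicate 1 in tissue markers. Depth does not account for it. CIH replicate 1 has the smallest total, so thinning to that total changed only the other libraries. At equal depth their dentate scores lay between -0.187 and 0.929, against -1.32 for CIH replicate 1. In that library 6 of 9 cortex genes were highest and 8 of 8 dentate genes lowest, and it had the highest scores for thalamus (0.61), striatum (0.61) and meninges (0.88) and the lowest for ependyma (-1.11) and CA3 and CA2 (-0.74). These values restate the pattern, so more neighbouring tissue, of cortex or another kind, and less dentate gyrus in the dissection stay open. An effect of CIH on dentate granule genes stays open too, with 1 of 3 CIH libraries below all controls.

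Tissue makeup may also show in the small RNA libraries, a hypothesis tested in 4 relations over the 6 library names, of which 2 did not pass. The myelin score correlated with miR-219a-2-3p (r = 0.945, exact permutation p = 0.0194, adjusted 0.0444; rho = 0.771, exact permutation p = 0.103, adjusted 0.206), with r = 0.959 after leaving out the 2 libraries farthest from the median. The choroid plexus score correlated with miR-204-5p (r = 0.874, exact permutation p = 0.0222, adjusted 0.0444; rho = 0.943, exact permutation p = 0.0167, adjusted 0.0668), with r = 0.994 after leaving out 2. On deviations from the group means these correlations were 0.975 and 0.818. The ependymal score and miR-449a-5p gave r = 0.923 (exact permutation p = 0.0472, adjusted 0.0629; rho = 0.486, exact permutation p = 0.356, adjusted 0.475), but r = -0.498 after leaving out 2, so that relation rests on those libraries. The erythroid score and miR-451-5p gave r = 0.281 (exact permutation p = 0.571, adjusted 0.571; rho = 0.314, exact permutation p = 0.564, adjusted 0.564), and -0.0642 after leaving out 2. By ranks none of the 4 passed after adjustment. miR-219a-2-3p is uncertain singly, and with the counts of overlapping names summed and the libraries scaled anew the myelin relation had r = 0.980 (exact permutation p = 0.00139, adjusted 0.00556; r = 0.999 after leaving out 2) and the choroid plexus relation r = 0.911 (exact permutation p = 0.00972, adjusted 0.0194; r = 0.966 after leaving out 2). Both then had rho = 1 (exact permutation p = 0.00278, the smallest that ranks of 6 libraries can give, adjusted 0.00556). The myelin sum pools 3 names and both arms. For miR-204-5p, miR-449a-5p and miR-451-5p no other name was summed, so only the new scaling moved their values. The ependymal and erythroid relations gave r = 0.910 (exact permutation p = 0.05, adjusted 0.0667) and 0.269 (exact permutation p = 0.593, adjusted 0.593). Whether the 2 sets share tissue stays open, since the labels do not state it.

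The third pattern is the clock. The mean of 6 genes that peak by day minus that of 4 genes in the opposite phase was higher in CIH by 0.398 log2 units (exact permutation p = 0.2, where 0.1 is the smallest possible). CIH replicate 1 had the lowest value of the CIH libraries (0.0443), so leaving it out raised the difference to 0.475, yet CIH replicate 2 (0.141) lay above control replicate 1 (0.137) by less than the control SD of 0.304. The score of the whole clock list was highest in CIH replicate 1, and for that score tissue makeup of that library stays open. Time of day at sampling cannot be told apart from an effect of CIH, since the labels give no sampling times.

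With 3 libraries per group there are 10 splits of the libraries, too few for a share under 0.05. The real split called 9 gene lists, 2 of the 10 splits, the real one included, called as many, and the highest other called 14. For mRNAs the real split and the highest other called 0. For miRNAs the real split called 0 and the highest other 2, and for miRNA lists these were 0 and 3. Any split matches a real split with 0 calls. The 10 of 10 splits with as many calls in each of these was thus fixed in advance and tells nothing about the groups. At an unadjusted p under 0.05, the split of control replicate 1, CIH replicate 1 and CIH replicate 3 against the rest gave 2833 genes against 319 for the real one, which points to a structure of the samples other than the groups.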
